A study of Drosophila melanogaster with 2 samples.

How the data were processed

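ChIP-seq peak lists from 2 biological replicates of 1 group were used, whole embryos aged 0 to 24 h whose chromatin was sonicated to 200 to 800 bp and pulled down with an antibody against green fluorescent protein, per the labels. The replicate numbers are the labels' own. Each replicate has a ranked list of candidate peaks and a thresholded list, and the series has a thresholded list, a conservative thresholded list and 2 ranked lists that combine the replicates. All are on the dm6 assembly, per the labels. The aligner, the peak caller and their versions are not given in the sources used here, and a control experiment that the labels name as possible was not used here.

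The signal value of each peak is a score the authors deposited, with no unit given in the sources used here, and it served to describe, rank and filter peaks within a list and to correlate the replicates with each other. The integer score of each peak, also deposited by the authors, was at least 830 in each of the 4 thresholded lists. The deposited lists also carry −log10 values of a q-value and, in the ranked lists, of the irreproducible discovery rate (IDR), a measure of how well 2 sets of peaks rank alike. Every thresholded peak is a peak of its ranked list with a −log10 IDR of at least 2, that is an IDR of at most 0.01. The column for the p-value holds -1 in every deposited list and was not used. A file that compares the replicates gives 2 further signal values per peak, and 85.2% of the intervals beside the first of them occur in the ranked list of replicate 1 and 79.2% of those beside the other in that of replicate 2. The combined thresholded list was taken from candidates called on both replicates together, and each replicate's own thresholded list from that replicate alone, as matched by their coordinates. Read totals are not in the peak lists, so the depth of each library is unknown, and the intervals given cover counting error over peaks or genes only.

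The genome was the RefSeq Release 6 assembly, which shares its arms and their lengths with dm6, and no peak ended beyond an arm. Genes came from Ensembl release 115, with 18164 genes and 35497 transcripts on 2L, 2R, 3L, 3R, 4 and X after transposable elements were removed, of which 13945 genes were protein-coding. Peak coordinates are printed counted from 1. Summit classes were taken in the order promoter (within 500 bp of any annotated start), 5′ untranslated region, coding exon, 3′ untranslated region, other exon, intron and intergenic.

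Overlap was at least 1 bp, with 1000 random placements of replicate 2 peaks on their chromosome as chance level. Shares per class and per arm were set against 1000 random sets of positions, two-sided, with Benjamini-Hochberg adjustment over the 7 classes, or over 6 when the promoter class was left out. A gene list was compared with 10000 random lists of protein-coding genes matched in 20 bins of gene length, two-sided, with adjustment over 18 lists: terminal, gap and maternal, pair-rule, segment polarity, homeotic, dorsoventral, mesoderm, endoderm, salivary gland and trachea, neural, early zygotic, Notch, receptor tyrosine kinase signalling, ribosomal proteins, proteasome, chemoreceptors, cuticle proteins and accessory gland proteins. Some genes are in several lists, such as fkh and hkb. Listed symbols that differed from the annotation (7 genes) were matched by their current symbol, and the last 5 lists were taken by the start of the gene name (RpL and RpS, Prosalpha, Prosbeta, Rpn and Rpt, Or, Gr and Ir, Cpr, Acp). The Acp names also take in the adult cuticle protein genes Acp1 and Acp65Aa, and the proteasome names take in paralogues ending in T or R. Motifs and hexamers were counted once per window of 50 bp either side of the summit on both strands and compared by Fisher's exact test, two-sided. GC-matched windows were drawn from 399300 random genomic windows, 1 for each summit, and all 7220 summits found a match.

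Named genes followed a rule: hkb, the protein-coding genes with the start nearest to the 10 peaks of highest signal value, up to 4 genes per list with the highest signal value among those with an assigned peak in the combined list and in both replicates' lists, and the terminal, gap and maternal, and endoderm genes without a peak. Groups, tests, lists, motifs, the naming rule and most alternatives were fixed before the data were examined. The alternatives were stricter overlap, the conservative list, the 50% of the peaks with the higher signal value, each replicate's own list, other distance limits, other ways to assign a peak to a gene, other chance levels, and other motif windows and backgrounds. Those added after seeing the data were GC-matched windows for hexamers, comparison motifs and classes, candidates matched on GC content and promoter position, gene lists matched on neighbouring starts, and peaks with a signal value of at least 20. The last was not run for hexamers or comparison motifs.

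The scripts were tested on simulated data. For overlap, 30% of 4000 planted peaks came out as 31.95%, chance overlap included. For gene lists of a single size, called at an unadjusted p under 0.05, 3% of unenriched lists were called. So were 93% of lists for which genes holding a peak were drawn 6 times as often. Power for smaller effects, other list sizes and adjusted p-values was not simulated. For hexamers, 0 were called with nothing planted, and 91% of hexamers planted in 3% of windows were called. Both sets of windows were random genomic ones, without the difference in GC content that summits have from their flanks. Calls that follow from base composition were therefore not simulated. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.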

Results

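Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos aged 0 to 24 h. The flies carried Huckebein, the zinc finger transcription factor encoded by hkb that acts at both ends of the early embryo downstream of the Torso receptor, as a fusion with green fluorescent protein, and chromatin was pulled down with an antibody against the fluorescent tag. There was 1 group with 2 biological replicates and no second condition, so the comparisons are those between the replicates, of peaks with the genome around them, and of gene lists with chance. The list that combines both replicates held 7220 peaks on the dm6 assembly with a median width of 384 bp, covering 2424 kb. Of these peaks 78.9% are exactly 384 bp wide, so width and covered length do not measure the extent of each site. Replicate 1 alone gave 5260 peaks and replicate 2 alone gave 4347 peaks. The number of reads behind each library was not used here, so depth is unknown, and the signal value of a peak is the authors' own score, which ranks peaks within a list.

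The first comparison asks how far the replicates found the same sites. The strongest sites were shared: the peak with the highest signal value lay 29 bp upstream of the start of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, at X:2703686-2704066, with a signal value of 2889 in the combined list, 1721 in replicate 1 and 1174 in replicate 2. Next came an intronic peak of CG11050 (FBgn0031836) at 2L:6612423-6612971, with 2633 in the combined list, 1511 in replicate 1 and 1107 in replicate 2. The remaining peaks of the top 10 had as their nearest starts PNPase (a mitochondrial polynucleotide phosphorylase, signal value 1980), CG14100 (1937), CG18549 (1893), CG13323 (1792), Chro (the interband protein Chromator, 1736), CenG1A (1733), mRpL41 (a mitochondrial ribosomal protein, 1701) and px (1694), and all 10 were present in both replicates. The Ugalt summit lies in the sequence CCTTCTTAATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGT and the CG11050 summit in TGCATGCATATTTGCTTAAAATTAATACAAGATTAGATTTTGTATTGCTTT, each with 25 bp on either side. The CG13323 start was 11921 bp from its peak, in intergenic sequence at 2R:13035148-13035521, and 8 of the 10 summits lay within 500 bp of a transcription start.

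Of the replicate 2 peaks, 3485 of 4347 (80.2%, 95% exact binomial interval 79.0 to 81.3) shared at least 1 bp with a replicate 1 peak, and of the replicate 1 peaks 3490 of 5260 did (66.3%, 65.1 to 67.6). Peaks placed at random on their chromosome gave 2.41% on average and at most 3.15% (permutation p = 0.002, the smallest that 1000 placements can give). Across 3240 pairs of peaks with summits within 100 bp of each other, the median distance between summits was 18 bp and the Spearman correlation of signal values was 0.860. Across all 94096 candidates of the ranked list that sets the replicates against each other, the Spearman correlation was 0.428 (bootstrap 95% interval 0.423 to 0.435), and it was 0.669 across the 8964 candidates that overlap the combined list. Peaks are not independent replicates, so these coefficients only describe the pair of libraries.

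**Figure D1:**
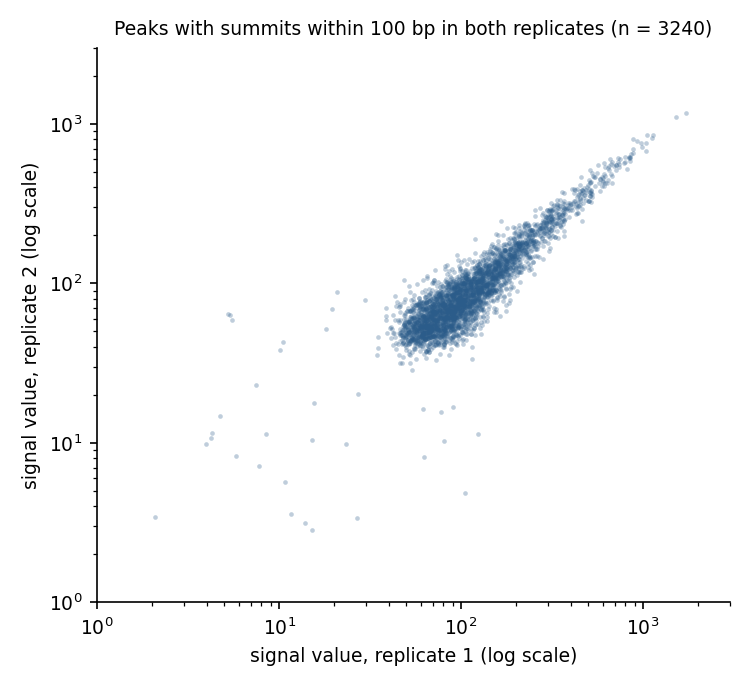
Signal value of each of the 3240 peaks with summits within 100 bp in both replicates, replicate 1 on the horizontal and replicate 2 on the vertical axis, both on log scales. Each point is 1 pair of peaks, and the Spearman correlation across the pairs is 0.860.

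Strong and weak peaks of the combined list differed in how often the replicates held them. In the quintile with the highest signal value, which includes the peaks at elav (a pan-neuronal RNA binding protein, 906), Z600 (a blastoderm cell cycle inhibitor, 877) and Raf (817), 99.1% of peaks overlapped a thresholded peak of both replicates. In the fourth quintile 4.85% did so and 43.9% overlapped a peak of neither, and in the lowest 12.3% and 60.0% did. Over the whole list, 3460 peaks (47.9%) were held by both replicates and 1604 (22.2%) by neither. Peaks found in replicate 1 alone had a median signal value of 56.3 against 97.5 for shared ones, and those found in replicate 2 alone 48.6 against 77.6.

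The second comparison asks where the peaks lay relative to genes. No control was used here, so peaks that do not depend on the tagged protein cannot be told from the rest. Summits lay at promoters: 3372 of 7220 (46.7%, 95% exact binomial interval 45.5 to 47.9) were within 500 bp of an annotated transcription start, against 13.6% of random positions, a 3.44-fold difference (permutation p = 0.002). Examples are the peaks at fkh, which encodes the fork head factor of the gut and salivary glands (3R:28585357-28585621, signal value 514, 227 bp upstream), at tin, the heart and visceral mesoderm homeobox gene (3R:21378606-21378907, 614, 202 bp upstream), and at gro, which encodes the corepressor Groucho (3R:26042376-26042648, 637, 155 bp upstream). The gro summit lies inside the gene, and its distance is to an annotated gro start further inside. Within this window 66.8% of summits lay upstream of the start, with a median position of -74 bp (interquartile range -172 to 38), against 47.1% of random positions in the same window. The median distance from a summit to the nearest start was 640 bp, against 3289 bp for random positions, and 6.81% of summits were over 10 kb away, against 23.5%.

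**Figure D2:**
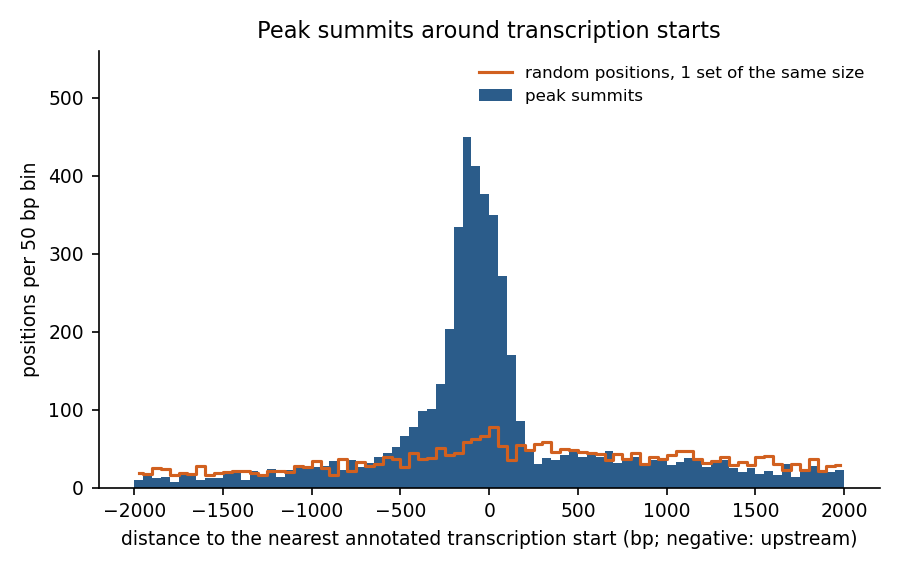
Number of peak summits (bars) and of random positions (line, 1 set of the same size) per 50 bp bin by distance in bp to the nearest annotated transcription start, with negative values upstream. The summits pile up just upstream of starts, with a median of -74 bp for those within 500 bp.

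Among the other annotation classes, introns held 37.3% of summits against 39.3% of bases (0.948-fold, adjusted permutation p = 0.0028), as in the peaks of Raf, aos, sog and dpp. Intergenic sequence held 12.6% against 27.4% (0.460-fold, adjusted permutation p = 0.0028). Coding exons held 0.623% against 13.7% (0.0455-fold) and 3′ untranslated regions 1.04% against 4.42% (0.235-fold), each with an adjusted permutation p of 0.0028. The share of coding exons was 0.456% in replicate 1, 0.345% in replicate 2 and 0.249% in the stronger 50% of the combined list, each below chance with the test passed. The 5′ untranslated regions outside promoters (0.693% against 0.776%, adjusted permutation p = 0.4855) and other exons (1.04% against 0.815%, 0.0676) did not pass the test; the summit in the 5′ untranslated region of cic, which encodes the repressor Capicua, is 1 of the former. The shares of introns and intergenic sequence depend on the promoter class: with promoter summits put back into the class beneath, introns held 49.3% of summits against 42.5% of bases (adjusted permutation p = 0.0024) and intergenic sequence 31.3% against 30.8% (adjusted permutation p = 0.3337).

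Peak density on the large arms was 55.4 peaks per Mb on 2L, 55.4 on 2R, 57.9 on 3L, 49.8 on 3R and 53.6 on X. The small chromosome 4 held 30 peaks, or 22.3 per Mb. The test below set only X against the large autosome arms. The list leaves out further peaks that pass the IDR threshold, 111 of them on 3R and 5 on X. The densities and the X ratios are therefore those of listed peaks. The embryos were not sexed, and males carry 1 copy of X. Per base, X had 0.986 times the density of the 4 large autosome arms, which did not pass the test (permutation p = 0.6693). Per protein-coding gene the ratio was 1.13 (permutation p = 0.002). Peaks per 100 such genes numbered 57.5 on X, 59.4 on 3L, 49.1 on 2R, 49.0 on 2L and 46.7 on 3R. A high value per gene was thus not particular to X.

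The third comparison asks which genes held peaks, starting with hkb itself. The hkb gene (FBgn0261434, 3R:4345015-4346646, minus strand) had 1 assigned peak, at 3R:4346783-4347166, with its summit 329 bp upstream of the start in the sequence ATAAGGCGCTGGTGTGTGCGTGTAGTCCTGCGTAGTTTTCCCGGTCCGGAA. Its signal value of 91.3 put it at position 4509 of 7220. Replicate 1 held this peak (48.2) and replicate 2 did not, where the highest candidate in the gene and the 1000 bp upstream had 41.2. Another pair of peaks lay downstream of the gene between 3R:4340933 and 3R:4341518 (97.6 and 9.60), both overlapping a peak of replicate 2 and none of replicate 1. The labels describe an insertion that targets hkb, and the number of hkb copies behind these values is not given in the sources used here.

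A summit was assigned to a gene when it lay inside the gene or within 1000 bp upstream of its start, and 4419 of 13945 protein-coding genes (31.7%) had at least 1 peak. Ribosomal protein genes stood out: 72 of 92 held a peak, against 19.2 expected from random lists of the same gene lengths (central 95% 12 to 27, ratio 3.74, adjusted permutation p = 0.0018, where 0.0002 is the smallest unadjusted value that 10000 lists can give). Of these 92 genes, 63 held a peak in replicate 1, 61 in replicate 2 and 57 in all 3 lists, and 71 had a summit within 500 bp of their own start. The highest signal values among those in all 3 lists were at RpL32 (530), RpL41 (428), RpL7 (419) and RpS27 (398). Their summits lay 121, 118, 33 and 13 bp upstream of the nearest own start, which for RpL7 is inside the gene. Some ribosomal protein genes have near-identical copies, such as RpS14a and RpS14b, whose reads cannot be told apart with certainty.

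Chemoreceptor genes, which encode odorant, gustatory and ionotropic receptors of adult and larval sense organs, held few peaks: 6 of 179 against 46.1 expected (ratio 0.130, adjusted permutation p = 0.0018), with 5 in replicate 1 and 4 in replicate 2. The difference was smaller against lists matched on holding a candidate peak (21.7 expected) and with 5000 bp upstream (30 against 71.8 expected), and passed the test in both (adjusted permutation p = 0.0018). The 3 with a peak in all 3 lists were Or88a (451), Gr32a (206) and Ir60e (109). Their summits lay 642, 798 and 280 bp upstream of the gene. Those of Or88a and Gr32a lay within 500 bp of another annotated start. Cuticle protein genes also held few peaks, at 5 of 70 against 15.4 expected (ratio 0.325, adjusted permutation p = 0.0024). The count was 3 in replicate 1 and 1 in replicate 2, and the Cpr73D peak had a signal value of 194. That call was lost by nearest start (9 of 70, 14.3 expected, adjusted permutation p = 0.2423) and against lists matched on holding a candidate peak (11.7 expected, adjusted permutation p = 0.0972). None of the 19 accessory gland protein genes held a peak (2.33 expected, adjusted permutation p = 0.4021), which allows a share of up to 17.6% by the exact binomial interval. Proteasome genes held peaks at 9 of 48 (10.5 expected, adjusted permutation p = 0.9768), with 5 in each replicate and with Rpn3 (336), Rpn13 (131) and Rpn5 (116) as examples.

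None of the 13 lists of developmental genes passed the test after adjustment over all 18 lists. Of the terminal genes, which specify the ends of the embryo and include hkb, 7 of 11 held a peak (4.64 expected, adjusted permutation p = 0.5080), 7 in replicate 1 and 6 in replicate 2, with gro (637), bowl (549), fkh (514) and cic (341) highest among those in all 3 lists, while tor, trk, tll and byn had none. Of the gap and maternal genes 5 of 14 did (5.65 expected, 4 in each replicate), with cnc (196), bcd (155) and nanos (110) in all 3 lists. The genes hb, Kr, kni, knrl, gt, oc, btd, slp1 and slp2 had none. Of the endoderm genes 8 of 10 did (4.73 expected, adjusted permutation p = 0.2646), 6 in replicate 1 and 4 in replicate 2, with fkh, Inx7 (266), GATAd (153) and dve (83.6) in all 3 lists and GATAe and mex1 without a peak. With each peak given to the gene with the nearest start, 9 of the endoderm genes held one (4.21 expected, adjusted permutation p = 0.0144). Salivary gland and tracheal genes held peaks at 14 of 21 (10.4 expected, adjusted permutation p = 0.4021) and at 8 in each replicate, among them fkh, klar (298), trh (293) and rib (269). With peaks counted only within 500 bp of their own starts, 13 held one and the test was not passed (7.18 expected, adjusted permutation p = 0.0648). With lists also matched on neighbouring starts, chosen after seeing the data, 6.67 were expected and it was passed (adjusted permutation p = 0.0306).

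Pair-rule genes held peaks at 3 of 10 (3.79 expected, 4 in replicate 1 and 3 in replicate 2), namely ftz-f1 (253), hry (142) and opa (99.7), and segment polarity genes at 10 of 14 (7.61 expected, 7 in replicate 1 and 5 in replicate 2), with nkd (391), Wnt4 (125), ptc (110) and Wnt6 (87.0). Homeotic genes did so at 8 of 11 (6.81 expected, 6 in replicate 1 and 4 in replicate 2), with hth (319), Antp (212), Abd-B (130) and Dfd (106). Dorsoventral genes did so at 8 of 17 (8.0 expected, 9 in replicate 1 and 8 in replicate 2), with ush (393), sog (333), dpp (330) and sim (308), where a further ush peak of 2349 passes the irreproducible discovery rate threshold and is absent from the list, and mesoderm genes at 11 of 18 (9.0 expected, 9 in replicate 1 and 8 in replicate 2), with tin (614), kirre (505), ths (369) and Mef2 (206). Neural genes had 5 of 20 (8.86 expected, 8 in replicate 1 and 5 in replicate 2), with elav (906), brat (652), grh (367) and insc (170). Early zygotic genes had 3 of 8 (2.59 expected, 3 in replicate 1 and 2 in replicate 2), with Z600 (877) and Sxl (198). Notch pathway genes had 5 of 12 (3.89 expected, 4 in each replicate), with N (418), E(spl)mdelta-HLH (264) and E(spl)m3-HLH (188). Genes of receptor tyrosine kinase signalling, a list that takes in Egfr as well as tor, had 10 of 14 (8.23 expected, 10 in each replicate). Among them were Raf (817), aos (604), spi (405) and aop (316), and the list was not split by receptor. In a single replicate some of these counts changed side against chance. Replicate 2 had fewer than expected for homeotic (5.35) and segment polarity genes (5.79), and replicate 1 for homeotic (6.05) and salivary gland and tracheal genes (8.84). Replicate 1 had more than expected for neural (7.47), dorsoventral (6.95) and pair-rule genes (3.05), as replicate 2 did for the last of these (2.72) and dorsoventral genes (6.18). No list of developmental genes passed the test in either replicate. In the short counts the members not named so far were D and ems (gap and maternal), D (neural), zld (early zygotic), E(spl)mbeta-HLH and Ser (Notch), and Cpr64Aa, Cpr65Av, Cpr65Ea and Cpr67Fb (cuticle), named here after their values were seen. An assigned peak can belong to a neighbouring gene: the Z600 and E(spl)mdelta-HLH summits lay 692 and 988 bp upstream of those genes and within 500 bp of another annotated start. The kirre summit, 3426 bp from the nearest start of kirre, also lay within 500 bp of another annotated start.

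**Figure D3:**
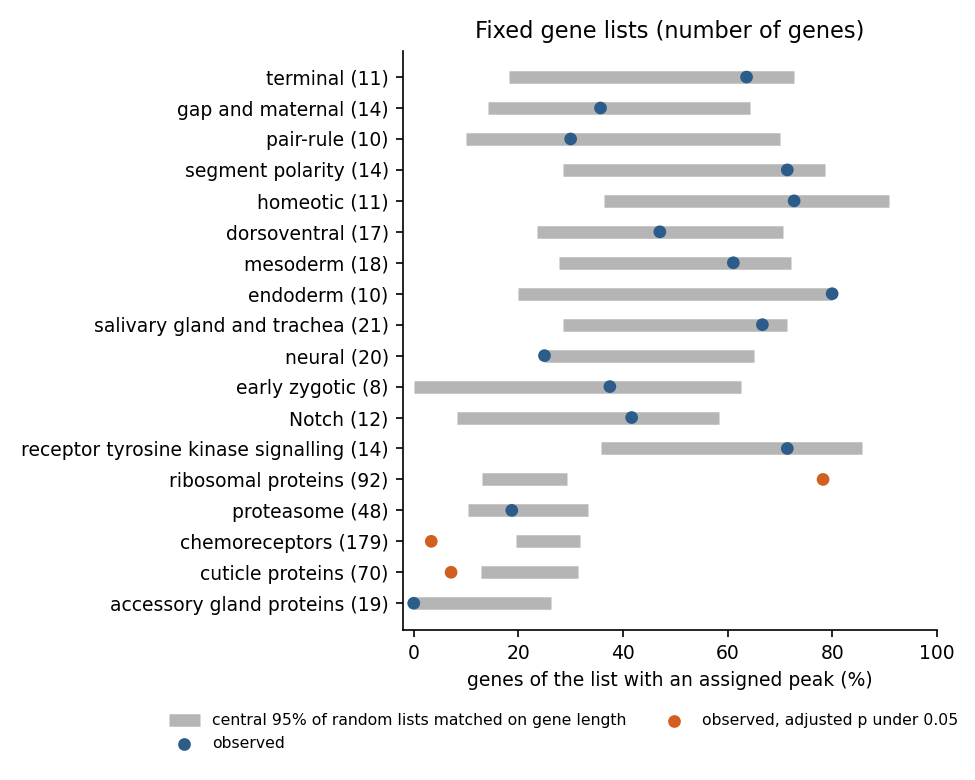
Percentage of genes with an assigned peak in each of the 18 fixed lists (points) with the central 95% of 10000 random lists matched on gene length (grey bars), number of genes in brackets. Ribosomal protein genes lie above their bar at 78.3%, chemoreceptor and cuticle protein genes below theirs at 3.35% and 7.14%, and the other 15 lists had an adjusted p of 0.05 or more.

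The fourth comparison asks which DNA sequences lay at the summits. The core CACGCCC, published for the Huckebein zinc fingers, was less frequent at summits than beside them: 55 of 7220 windows reaching 50 bp to either side held it (0.762%), against 184 of 14440 windows centred 500 bp away (1.27%), an odds ratio of 0.598 (95% interval 0.443 to 0.809, Fisher's exact p = 0.000539). It ranked 24 of the 42 orders of its 7 bases by this ratio, and 41 of the 42 orders were less frequent at summits. Against genomic windows of the same GC content the odds ratio was 0.733 (0.518 to 1.04, Fisher's exact p = 0.0938), which did not pass the test. Its share was 0.277% in the quintile of peaks with the highest signal value, 1.39% in the fourth quintile and 0.970% in the lowest.

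Summits were rich in A and T. GC content averaged 36.2% ± 10.9 (SD over 7220 windows), against 42.3% ± 10.4 at 500 bp, 44.9% ± 10.3 at candidates outside the thresholded peaks and 42.2% ± 10.4 at random positions. It fell with signal value, from 41.5% in the lowest quintile to 30.5% in the highest, and the Spearman correlation of signal value with GC content across peaks was -0.371 in the combined list, -0.367 in replicate 1 and -0.353 in replicate 2. Among candidates outside the thresholded peaks it was -0.00508. Median peak width was 225 bp in the highest quintile and 384 bp in the others, and whether summits are placed alike at both widths was not tested. Across the quintiles with a median width of 384 bp, GC content also fell with signal value, from 41.5% to 33.4%. Of all hexamers, 433 were more frequent and 939 less frequent at summits than 500 bp away (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). All 36 hexamers made only of A and T were among the 433, led by AAATAT (30.4% of summits against 17.2%) and TTAAAA (28.1% against 15.9%). With windows of the same GC content as background, chosen after seeing the data, 193 hexamers were more frequent, 71 of them shared with the 433, led by ACAGTG (6.66% against 3.28%), ACACTG (6.54% against 3.20%) and AGAGCG (4.94% against 2.20%). Of the 36 hexamers made only of A and T, 6 were among the 193, and 207 hexamers were less frequent.

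**Figure D4:**
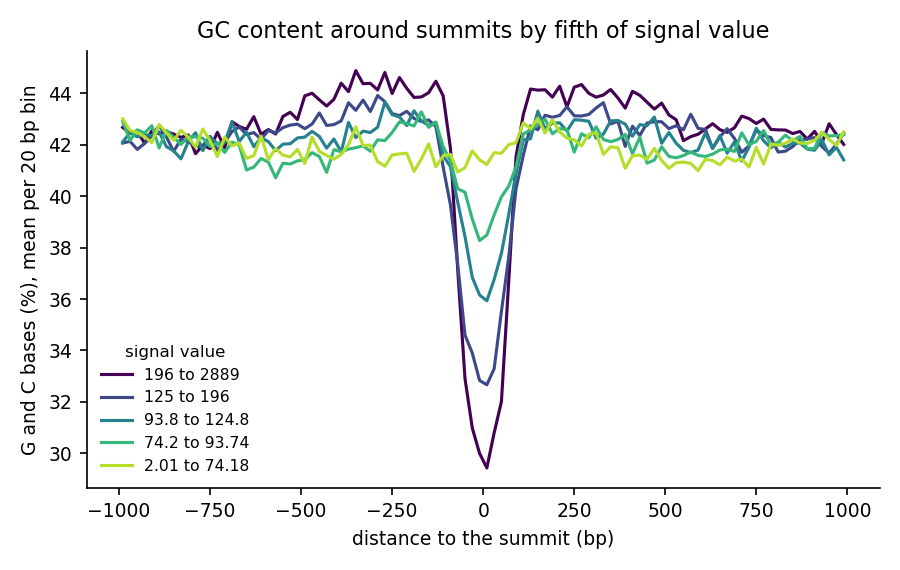
Mean percentage of G and C bases per 20 bp bin from 1000 bp before to 1000 bp after the summits, with 1 line for each quintile of the combined list by signal value (1444 peaks each). The highest quintile has the deepest dip at the summit, and the mean within 50 bp of the summit is 30.5% there and 41.5% in the lowest quintile. Median peak width is 225 bp in the highest quintile and 384 bp in the others.

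Sites of other embryonic factors were compared in the same way, with 8 motifs fixed beforehand. The M1BP site GGTCACACT was more frequent at summits, 0.526% against 0.118% (4.47-fold, exact adjusted p = 2.73e-07), and so was TATCGATA, the site of BEAF-32 and DREF at gene boundaries (0.789% against 0.353%, 2.24-fold, exact adjusted p = 9.11e-05). Both kept this direction and passed the test against GC-matched windows (9.50-fold and 2.11-fold), of which only 0.0554% held the M1BP site. Neither background was matched on promoter position, and promoters held 46.7% of summits against 13.3% of GC-matched positions. Whether these sites are more frequent than at other promoters was therefore not tested. The GAGA factor repeat GAGAGAG was at 2.48% against 2.21% beside the summits (exact adjusted p = 0.263) and at 0.956% in GC-matched windows (2.59-fold, exact adjusted p = 1.01e-11). The Caudal site TTTATG was more frequent than beside the summits (1.16-fold, exact adjusted p = 0.000268) and not than in GC-matched windows (0.947-fold, 0.247). The E-box CACGTG (0.652-fold, exact adjusted p = 0.00558) and the Snail site CAGGTG (0.625-fold, 1.92e-07) were less frequent than beside the summits and did not pass against GC-matched windows (0.938-fold and 0.862-fold). The Zelda site CAGGTAG (1.02-fold, exact adjusted p = 0.924) and the Bicoid site TAATCC (0.904-fold, 0.263) did not pass against flanks; against GC-matched windows they were at 1.68-fold (0.0788) and 0.799-fold (0.0304).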

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

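What follows was counted only after the result was seen. The thresholded list of both replicates leaves out 168 peaks on the main arms that pass the same IDR threshold in the ranked list it was drawn from, a signal in data outside the comparisons above. They are not weak, with a median signal value of 116 against 107 for listed peaks. The strongest, at 2L:480893-481273, would stand 3rd in the whole ranked list with 2349. Its nearest start is that of cbt at 1397 bp, and it is assigned to ush of the dorsoventral list, whose strongest listed peak has 393. The next lay nearest to Lk6 (1579), larp (1163), CG18428 (1126) and tara (956). Of the 168 peaks, 111 lie on 3R (66.1%, against 22.1% of listed peaks), 38 on 2L, 7 on 2R, 7 on 3L, 5 on X and 0 on 4, and 141 start within 10 kb of another peak that was left out. They cover 71 protein-coding genes that have no listed peak, among them RpL13A (222) of the ribosomal protein list and Ras85D (139) of the receptor tyrosine kinase list, so the counts for both lists are counts of listed peaks. The accompanying text of the lists names a further file among their origins, which was not analysed here, and no explanation was tested.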

How the results depend on the processing

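No paired analysis was possible because there is only 1 group. Overlap and start share kept their direction and call under each setting run, and arm density per base passed under none. Alternatives chosen after seeing the data were the signal minimum of 20 and GC-matched windows for hexamers, comparison motifs and classes. So were candidates matched on GC content and promoter position, and lists matched on neighbouring starts. Of the settings for main results 122 were counted as unchanged, and of those for single lists and motifs 158 kept their call. Of the latter settings 12 gained a call, 2 lost it on the same side and TTTATG lost it and turned. Unchanged refers to the call where a test was run, and results that did not pass could change side against chance. Settings in which the lists with fewer peaks than chance numbered 3 instead of 2, given below, were also counted as unchanged. The replicate correlation of 0.428 moved to 0.669 for candidates overlapping the combined list, 0.528 as Pearson correlation of log2 values and 0.314 at a signal value of at least 20. The core motif ratio of 0.598 lost its call at 25 bp either side (0.826), against GC-matched windows (0.733) and against candidates matched on GC content and promoter position (0.995). It was lower in the stronger 50% of the peaks (0.327), in replicate 2 (0.426) and against candidates outside the peaks (0.401), each past the test. TTTATG turned to 0.947 and enriched hexamers fell from 433 to 193 with GC-matched windows. Lists with more peaks than chance numbered 1, and 2 by nearest start, 7 by Fisher's exact test without length matching and 2 when matched on neighbouring starts, where salivary gland and trachea joined. Lists with fewer numbered 2, and 1 by nearest start and 1 when matched on candidates, since the cuticle count of 9 (adjusted permutation p = 0.2423) and 5 (0.0972) lost their call. They numbered 3 with 5000 bp upstream, where neural genes joined (5 against 10.8 expected, adjusted permutation p = 0.0468), and 3 by Fisher's exact test, where accessory gland genes joined (adjusted p = 0.0041). Per gene, the X ratio was 1.13 and passed, though 3L had more peaks per gene than X. Without a promoter class, whose summits then join the class beneath, shares were 13% for 5′ untranslated regions and 2.95% for other exons, both now past the test, and 49.3% for introns and 31.3% for intergenic sequence, both turned. In the stronger 50% of the peaks, introns (38.1%) lost their call. Leaving out a replicate, 5′ untranslated regions ranged from 0.483% without replicate 1, which passed (adjusted permutation p = 0.0326), to 0.703% without replicate 2. The cause of the remaining changes was not tested. With 2 libraries of unknown depth, absence of a peak is not absence of binding.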

Other observations

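Of the tests below, those on other sets of constitutively expressed genes, on lists matched on neighbouring starts and on candidates under peaks of 1 replicate were chosen only after the result they bear on was seen, and so were the gene sets of the first paragraph. For the tests on neighbouring starts and on candidates, what each outcome would mean was written before their own values were seen. Mitochondrial ribosomal protein genes held peaks at 27 of 73, against 12.3 expected for their lengths (ratio 2.20, adjusted permutation p = 0.0014 over 7 sets), with 17 in replicate 1 and 18 in replicate 2. Genes of the mitochondrial respiratory chain did so at 26 of 87 (18.2 expected, adjusted permutation p = 0.1218), translation factors at 22 of 52 (16.3 expected, 0.1859), aminoacyl-tRNA synthetases at 13 of 32 (10.4 expected, 0.5799) and heat shock protein genes at 6 of 19 (5.30 expected, 0.8917). Histone genes held few, 2 of 115 (11.9 expected, adjusted permutation p = 0.0021). They lie largely in a tandem array of near-identical copies where reads cannot be placed with certainty.

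At ribosomal protein genes, the 76 summits within 500 bp of these starts sat at a median of -9 bp (interquartile range -33 to 23), against -74 bp for all summits near starts, and had a median signal value of 159 against 107 for the whole list. Their GC content was 44.3% ± 7.92 (SD), against 38.2% ± 11.8 for promoter summits as a whole and 30.5% for the quintile of all peaks with the highest signal value. Of the 76, 55 overlapped a peak of both replicates. These differences were not tested.

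Ribosomal protein genes are short and lie among other genes, so that promoters of neighbours could supply their peaks. With peaks counted only within 500 bp of the genes' own starts, and random lists matched on length and on the number of other starts within 2000 bp, 71 genes held a peak against 17.6 expected (central 95% 11 to 25, ratio 4.04), which argues against that explanation. Another is that constitutively expressed genes hold peaks in general. Mitochondrial respiratory chain, mitochondrial ribosomal protein and proteasome genes as 1 set gave 62 of 208 against 41.0 expected, a ratio of 1.51 (1.21 to 1.85 by resampling genes). This lies below 1.87, the ribosomal ratio divided by 2, a bound written after values were seen and given without a spread. Without proteasome paralogues whose names end in T or R the interval of 1.31 to 1.98 includes that bound. The pooled sets also differ, with ratios of 1.43 for the respiratory chain, 2.20 for mitochondrial ribosomal proteins and 0.857 for the proteasome. The comparison therefore cannot decide, and this explanation stays open. No biological explanation was tested, since the design holds no embryos without the tagged protein.

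The depletion of CACGCCC at summits may follow from their low GC content. Against genomic windows of the same GC content the odds ratio was 0.733 with a 95% interval that includes 1 (0.518 to 1.04), as that explanation predicts, and 41 of the 42 orders of the same bases were also less frequent at summits than beside them. Against GC-matched windows the median ratio over the 42 orders was 0.966, while that of the core was 0.733 and ranked 36. In the comparison given above with candidates matched on GC content and promoter position, added after seeing the data, the odds ratio was 0.995. Its 95% interval of 0.685 to 1.45 is wide enough to hold 0.733 as well. No enrichment of the core was found in any of these comparisons, and whether a depletion of its own remains beside that of composition stays open. Whether the tagged protein reached these sites through other factors was not tested.

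Peaks found in only 1 replicate may be sites that both hold, with the threshold falling between them. Of 2632 such peaks, 2525 (95.9%) shared a base with a candidate of the other replicate. For replicate 1 peaks this share was 96.0% against 31.5% for random placements, and for replicate 2 peaks 95.8% against 35.3%. The placements were uniform along each chromosome, whereas peaks and candidates both gather near starts, so this chance level is low. Of the pooled candidates outside the thresholded peaks, 18.8% lay within 500 bp of a start, against 13.6% of random positions. The overlapping candidates had median percentiles of 91.5 and 92.1 by signal value in their own ranked lists. A difference in depth between the libraries stays open, since depth is unknown.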
